A study of Mus musculus with 6 samples.

How the data were processed

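Messenger RNA was sequenced from 6 mouse brains taken at embryonic day 14.5, 3 labelled wild type (WT) and 3 labelled E4f1 knockout (KO). Per the labels' protocols, the embryonic brains were dissected and flash frozen, RNA was taken up in Trizol, and stranded mRNA libraries were made with a KAPA kit and read from both ends. The submitters' processing notes name FastQC, Trimmomatic, STAR (version 2.5.3a) and RSEM (version 1.2.28), and the builds mm10 and GRCm38. The order and settings of these steps are not given in the sources used here, and neither is the strand setting of the counting.

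Per the file headers, the deposited tables give for each gene an expected count, a TPM and an FPKM, with a list of RefSeq transcripts. An expected count is the number of read pairs that RSEM assigns to a gene, with pairs that fit several transcripts shared out by estimate. Of these deposited expected counts, between 98.9% and 99.0% per library lay within 0.005 of a whole number. The TPM values, also deposited by the authors, are scaled to transcript length and to the same total in each library, and keep no depth. The FPKM column deposited by the authors was not used. Genes were named by their symbols as the tables give them. Of the 15848 genes tested, 15824 matched a symbol or an unambiguous synonym in the RefSeq gene table of GRCm38, from which coordinates were taken; exon overlaps, divergent starts and codons were taken from GENCODE.

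The expected counts were rounded to whole numbers and tested with edgeR (version 4.0.16). Genes were kept by filterByExpr with the groups given, libraries were scaled by TMM, and KO was compared with WT by the quasi-likelihood F test with robust estimation, two-sided. P-values were adjusted by Benjamini and Hochberg over all tested genes, and a gene is called changed at an adjusted p below 0.05. Unless another tool is named, every adjusted p of a gene comes from this edgeR test. Fold changes are log2 values of KO minus WT, each with the standard error (SE) that corresponds to its F statistic. Levels are CPM, counts brought to the same library total, after TMM scaling, as the mean ± SD of 3 libraries.

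The gene lists, the rule for named genes and the alternatives were set before the data were examined, except where said otherwise. From general knowledge, 38 gene lists were written: E4F1 targets reported in the literature, pathways of pyruvate use, tRNA modification, stress and metabolism, and markers of cell types, brain regions, tissue left on the brain, sample handling, neighbours of E4f1 and sex. The list of 13 mitochondrially encoded genes matched no symbol and was not analysed here, and 37 lists with at least 3 tested members were tested with limma's camera (version 3.58.1) at a preset correlation of 0.01 between genes, with Benjamini and Hochberg adjustment over the lists. Each list was tested again with the correlation estimated from the data, and with fry, whose p asks whether the genes of a list move on balance in one direction and does not compare them with other genes. Calls within a list were also counted with p-values adjusted over the list alone.

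The genes named in the text follow a rule: E4f1, the members of the 3 lists on E4F1 targets, pyruvate and Elongator, up to 4 called members of each other list with the largest absolute fold change, the 10 genes with the largest change in each direction, and the 10 genes with the smallest p. For the last 2 parts, predicted gene models (symbols of Gm and a number, or ending in Rik), pseudogenes and sex-linked genes were left out. The 10 largest changes in each direction were also limited to called genes with a mean of at least 1 CPM and with no overlap between the groups. The values of a few genes within the rule are not reported here. All genes given with values outside this rule, such as En1, En2 and Eci1, were chosen after their values were seen.

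The alternatives were DESeq2 (version 1.42.0), limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1) with a TPM of at least 1 in 3 libraries, other scalings and filters on low counts, non-robust estimation, the replicate number or the animal number as a block, WT 1, WT 2, KO 1 and KO 2 alone (whose animal numbers lie close together), leaving out each library, and leaving out erythroid, mitochondrial and sex-linked genes. Analyses without Rn45s and with a midbrain score as a covariate (the mean log2 CPM of En1, En2 and Pax5) were added after the data were seen, as were marker lists of phagocytic and resident microglia, of midbrain and diencephalon and of telencephalon, scored as the mean log2 CPM of their genes, and the lists of meninges and endothelium were scored likewise.

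Pairs of libraries from one group differed far more than sampling noise: the chi-square of their counts per degree of freedom was between 45.2 and 175, so none was counted as a repeat of another. The edgeR test was checked on simulated counts with 15729 tested genes, of which 200 were changed, in groups of 3. It recovered 14.5% of the genes changed 1.5-fold, 55.7% of those changed 2-fold and 92.6% of those changed 4-fold, and 4.31% of its calls were false. DESeq2, with 15845 genes tested, recovered 45.2%, 82.9% and 95.6%, and 28.8% of its calls were false. In this simulation, at this group size and depth, most 1.5-fold changes were missed by the edgeR test. The counts came from a single run, with genes drawn independently at the dispersions that edgeR had estimated. The shares of false calls therefore need not hold for the real data.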

Results

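E4F1 is a zinc finger transcription factor, and the series asks how its loss alters pyruvate metabolism and the Elongator complex, which modifies tRNAs, in the developing brain. Transcripts were measured by RNA-seq in the brains of 3 WT and 3 E4f1 KO mouse embryos at E14.5. The expected counts summed to 74064707, 42113465 and 69915149 in WT 1 to WT 3 and to 69068011, 56149990 and 50186590 in KO 1 to KO 3. The tables list 24848 genes, of which 15848 were expressed highly enough to be tested. Spearman's correlation of log2 CPM across genes was between 0.982 and 0.994 within the groups and between 0.970 and 0.991 between them. The labels give each brain its own animal number but do not state litters or the sex of the embryos. Xist, which is transcribed in females, reached 2477, 2638 and 2442 CPM in WT 1, KO 1 and KO 3, while the Y-linked Ddx3y was found at 38.0, 38.7 and 40.0 CPM in WT 2, WT 3 and KO 2, so both groups held both sexes.

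E4f1 itself (chromosome 17, 24443778 to 24455392, GRCm38) stood at 20.7, 21.6 and 21.5 CPM in the WT libraries and at 7.12, 7.01 and 6.92 CPM in the KO libraries. It fell to 0.330 of its WT level in KO, with a log2 fold change of -1.60 ± 0.08 (SE, n = 3 per group, edgeR adjusted p = 0.00142). The labels do not say which exons the allele removes or whether all cells of the brain carry the deletion. A count over the whole gene in whole tissue cannot separate transcripts of a deleted allele from intact ones.

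In KO brains, 159 genes changed, 81 higher and 78 lower, and 76 of them by at least 2-fold. The balance of directions depended on the settings. Scaling by library totals called 123 higher and 63 lower, and the replicate number as a block 24 higher and 42 lower. Rad52, Nsun5, Tube1, Dnajc19 and Dph5 had the largest decreases, and Trib3, Clec7a, Chac1, Eif4ebp1 and Ccl6 the largest increases, among the called genes that the naming rule admits. Elp3, the catalytic subunit of Elongator, had the smallest p of all tested genes and fell to 0.179 of its WT level. Groups did not overlap in any of the 159 genes, which largely follows from selecting them on these same values. Of all tested genes, 27.6% had no overlap, against a chance share of 10%. The count depended on single libraries: it was 63 without WT 1, 82 without WT 2, 52 without WT 3, 36 without KO 1, 71 without KO 2 and 69 without KO 3, and 34 of the 159 genes (12 higher, 22 lower) were called in each of these 6 fits. DESeq2 called 1437 genes, all 159 among them. The libraries also differed in midbrain genes, with En1, chosen after its values were seen, at 18.6, 10.4 and 1.71 CPM in WT 1 to WT 3 and between 0.112 and 0.960 CPM in KO. With a midbrain score as a covariate, added after the data were seen, and with WT 1, WT 2, KO 1 and KO 2 alone, whose animal numbers lie close together, edgeR called 0 genes, against 753 and 1546 at an unadjusted p below 0.05. E4f1 had -1.65 ± 0.16 and -1.57 ± 0.13 in these 2 fits, against -1.60 ± 0.08 in the main fit. Its call ended with a fold about as large and a wider SE. Fewer residual degrees of freedom alone do not account for this in the fit with the midbrain score. The replicate block leaves no more of them and called 66 genes, with E4f1 at an adjusted p of 0.0168. That block keeps all libraries, so it cannot tell whether the loss in the other fit comes from its smaller number of brains. The score of En1, En2 and Pax5 was 4.12, 3.18 and -0.19 in WT 1 to WT 3 and -3.05, -1.31 and -1.97 in KO 1 to KO 3. It was thus higher in every WT library, and a fit with this covariate cannot fully separate it from genotype.

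Several known E4F1 targets fell in KO. Of the 11 tested members of this list, 6 fell and none rose (7 fell when adjusted over the list alone), and all 11 fold changes were negative, with a median of -0.80. Elp3 (chromosome 14, 65530446 to 65593112) went from 121 ± 4.70 to 21.6 ± 1.62 CPM (log2 fold change -2.49 ± 0.08, adjusted p = 4.81e-04). Dlat, the E2 subunit of the pyruvate dehydrogenase complex (chromosome 9, 50634633 to 50659780), went from 45.4 ± 1.8 to 6.62 ± 1.09 CPM (-2.78 ± 0.14, adjusted p = 0.00142). Dnajc19, a co-chaperone of the mitochondrial inner membrane, fell by 2.99 ± 0.20 (adjusted p = 0.00210), and Taz, the tafazzin gene that remodels cardiolipin, fell by 2.89 ± 0.17 (adjusted p = 0.00197). Ndufs5, a subunit of respiratory complex I, fell by 2.15 ± 0.30 (adjusted p = 0.0409), and Pdpr, the regulatory subunit of pyruvate dehydrogenase phosphatase, fell by 0.80 ± 0.08 (adjusted p = 0.0114). The other 5 members, among them Mpc1, Chek1, Dld and Bcs1l, did not pass the test. Mpc1, a subunit of the mitochondrial pyruvate carrier, had a log2 fold change of -0.71 ± 0.12 and an adjusted p of 0.0611. DESeq2 called it lower (adjusted p = 2.60e-05), as did limma on log2(TPM + 1) and log2(TPM + 0.1) (0.0346 and 0.0351), and each of these 3 fits called 7 targets lower. The list as a whole was lower by camera (adjusted p = 1.35e-20; adjusted p = 0.0375 with an estimated correlation; fry adjusted p = 2.21e-04). Elp3, Dlat, Taz and Dnajc19 were called in all 6 fits that left out 1 library. Ndufs5 was called only without KO 1 (adjusted p = 0.0313) and had an adjusted p of 0.0826, 0.0984, 0.154, 0.0988 and 0.124 without WT 1, WT 2, WT 3, KO 2 and KO 3, and Pdpr lost its call without WT 3, KO 1, KO 2 and KO 3 (0.0787, 0.112, 0.0571 and 0.0604).

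**Figure D1:**
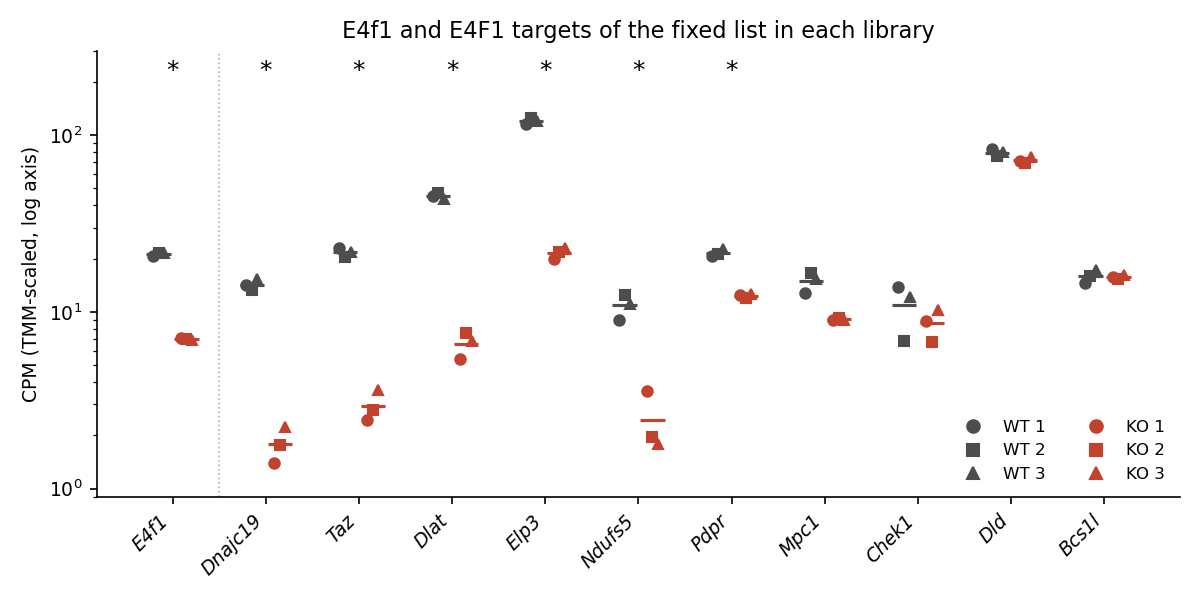
Level of E4f1 and of 10 of the 11 tested E4F1 targets in each library, in CPM on a log axis, with WT in grey, KO in red, a symbol per replicate and a bar at each group's mean; an asterisk marks an adjusted p below 0.05. The groups do not overlap for E4f1 and the 6 called targets, while Bcs1l (log2 fold change -0.02) and Dld (-0.15) have the smallest fold changes.

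Most other genes of the pathways that these targets belong to did not pass the test. Among 20 tested genes of pyruvate dehydrogenase and mitochondrial pyruvate supply, only Dlat and Pdpr fell and none rose (3 lower and 1 higher when adjusted over the list alone, by DESeq2 and at an unadjusted p below 0.05). Of the other catalytic subunits, Pdha1 had a log2 fold change of 0.06 ± 0.07 and Pdhb of -0.10 ± 0.06. Among 15 tested genes of Elongator and of the modification of the wobble uridine of tRNAs, Elp3 alone fell, whether adjusted over all genes or over the list alone. At an unadjusted p below 0.05 there were 4 lower genes, and DESeq2 called 2 of them. Besides Elp3, the 4 were Dph3 (log2 fold change -0.31 ± 0.08, DESeq2 adjusted p = 0.0305), Alkbh8 (-0.26 ± 0.08) and Urm1 (-0.24 ± 0.08). Elp2, Elp4 and Elp5 had log2 fold changes of 0.03 ± 0.07, -0.01 ± 0.09 and 0.10 ± 0.05. The pyruvate list did not pass camera (adjusted p = 0.0746; adjusted p = 0.356 with an estimated correlation; fry adjusted p = 0.00724), and passed without KO 3 (adjusted p = 0.0282) and without a filter on low counts (0.00599). The Elongator list was lower at the preset correlation (adjusted p = 0.0174) and not with an estimated one (adjusted p = 0.356 with an estimated correlation; fry adjusted p = 0.00385), and its call ended without WT 1 (adjusted p = 0.0902) and without the genes it shares with other lists, such as Elp3 (0.313). The medians of both lists, -0.05 and -0.05, turned positive (0.01 and 0.01) when libraries were scaled by their totals alone.

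**Figure D2:**
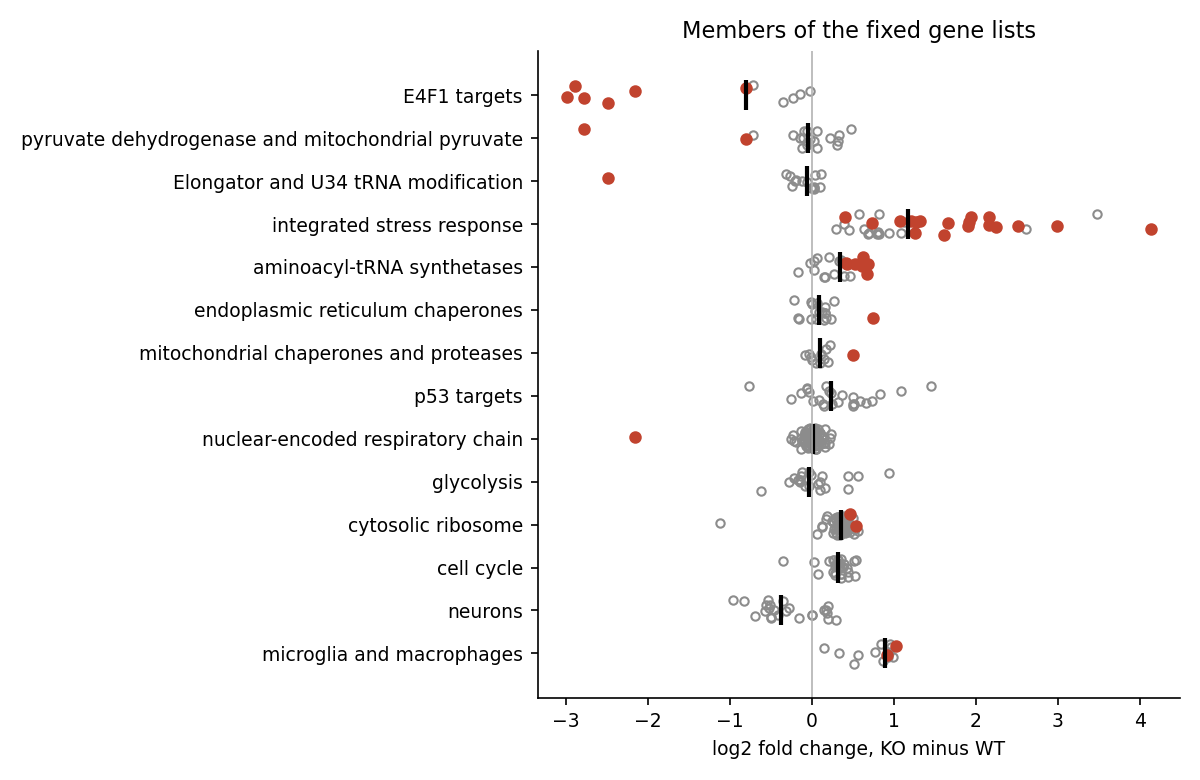
Log2 fold change (KO minus WT) of every tested member of 14 of the fixed gene lists, with members called changed as filled red points, others as open circles, and the list's median as a black bar. Single genes stand far to the left in the pyruvate, Elongator and respiratory chain lists, while the integrated stress response list lies to the right with a median of 1.17.

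Outside the E4F1 target list, genes with varied functions had the largest decreases. Rad52, a DNA strand annealing protein, fell from 8.20 ± 0.244 to 0.817 ± 0.311 CPM (log2 fold change -3.33 ± 0.28, adjusted p = 0.00567). Nsun5, a methyltransferase of ribosomal RNA, fell from 13.8 ± 0.190 to 1.53 ± 0.371 CPM (-3.18 ± 0.19, adjusted p = 0.00197). Dph5, an enzyme of diphthamide synthesis on elongation factor 2, fell by 2.89 ± 0.18 (adjusted p = 0.00197), and Senp8, the protease that processes NEDD8, fell by 2.83 ± 0.20 (adjusted p = 0.00248). Neurl4, a centriolar protein, was the most abundant of the 10 and fell from 195 ± 8.05 to 28.4 ± 6.91 CPM (-2.78 ± 0.18, adjusted p = 0.00210). Tube1, the gene of epsilon-tubulin, and Fam229b, which lie side by side on chromosome 10, had log2 fold changes of -3.06 ± 0.22 and -2.86 ± 0.37 (adjusted p = 0.00252 and 0.0312). Among the genes with the smallest p, Tti2, a partner of the kinases of the PIKK family, fell by 2.14 ± 0.10 (adjusted p = 0.00134), Leo1, of the PAF transcription complex, by 1.69 ± 0.08 (adjusted p = 0.00142), and Znhit6, a factor of small nucleolar RNP assembly, by 2.77 ± 0.15 (adjusted p = 0.00161). The adjusted p of Rad52 was 0.0517 without KO 1, and that of Fam229b was between 0.0187 and 0.126 over the 6 fits that left out 1 library, below 0.05 only without KO 3.

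Genes of the integrated stress response rose together in KO. Of 34 tested members, 18 rose and none fell (32 rose when adjusted over the list alone), and all 34 fold changes were positive, with a median of 1.17. Trib3, a pseudokinase induced by CHOP, rose 17.6-fold, from 0.435 ± 0.223 to 7.78 ± 1.01 CPM (log2 fold change 4.13 ± 0.38, adjusted p = 0.00851). Chac1, a glutathione-degrading enzyme, rose 7.92-fold (2.99 ± 0.21, adjusted p = 0.00254), Eif4ebp1, a repressor of translation initiation, rose 5.70-fold (2.51 ± 0.15, adjusted p = 0.00197), and Sesn2, a leucine sensor upstream of mTORC1, rose 4.74-fold (2.24 ± 0.09, adjusted p = 0.00103). Atf5, Stc2, Cebpb and the proline synthesis gene Pycr1 also rose, with log2 fold changes of 2.16 ± 0.11, 2.16 ± 0.19, 1.95 ± 0.29 and 1.62 ± 0.09. The list was higher by camera (adjusted p = 5.59e-62; adjusted p = 0.0375 with an estimated correlation; fry adjusted p = 6.07e-04). The count of 18 became 10 without WT 3 and 9 without KO 1. Sesn2, Atf5, Chac1, Eif4ebp1 and Pycr1 were called in each of the 6 fits, whereas Cebpb was called in none of them (adjusted p between 0.0788 and 0.255), Trib3 lost its call without KO 1 (adjusted p = 0.0700) and Stc2 without KO 1 (0.0687) and WT 3 (0.0550). With the midbrain score as a covariate no member was called, Sesn2 having 2.21 ± 0.20 and a wider SE, although the list test held (adjusted p = 6.97e-48).

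**Figure D3:**
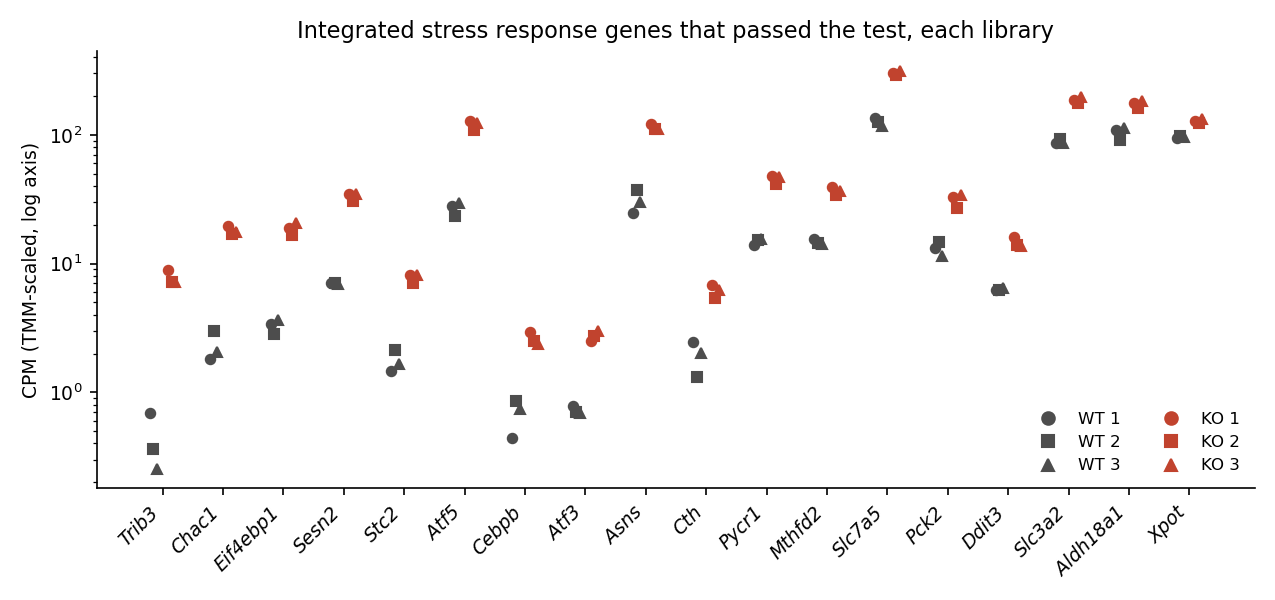
Level in each library, in CPM on a log axis, of the 18 integrated stress response genes called higher in KO, in order of fold change, with WT in grey, KO in red and a symbol per replicate. The KO libraries lie above every WT library for each of the 18 genes, from Trib3 to Xpot.

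Some enzymes that charge tRNAs also rose. Among 20 cytosolic aminoacyl-tRNA synthetases, 7 rose and none fell (12 rose and 1 fell when adjusted over the list alone), with a median of 0.35. Cars rose 1.61-fold, from 47.3 ± 1.18 to 76.2 ± 2.21 CPM (log2 fold change 0.69 ± 0.06, adjusted p = 0.00567), Iars 1.60-fold (0.68 ± 0.10, adjusted p = 0.0456), Mars 1.55-fold (0.63 ± 0.06, adjusted p = 0.0109) and Yars 1.52-fold (0.61 ± 0.05, adjusted p = 0.00703). The list was higher at the preset correlation (adjusted p = 2.09e-12) and not with an estimated one (adjusted p = 0.186 with an estimated correlation; fry adjusted p = 0.00385). Cars was not called without KO 1 (adjusted p = 0.0700), Yars without WT 3 and KO 1 (0.0560 and 0.0846), Mars without WT 3, KO 1 and KO 3 (0.0781, 0.110 and 0.0678), and Iars in none of the 6 fits (between 0.0722 and 0.255). The 7 calls became 3 without WT 1, 4 without WT 2, 1 without WT 3, 0 without KO 1, 3 without KO 2 and 2 without KO 3.

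Neighbouring stress pathways held single calls. Herpud1 alone rose among 19 tested chaperones and quality control genes of the endoplasmic reticulum, 1.67-fold (log2 fold change 0.74 ± 0.07, adjusted p = 0.00914; 2 rose when adjusted over the list alone), and Hspa9 alone among 12 mitochondrial chaperones and proteases, 1.42-fold (0.51 ± 0.07, adjusted p = 0.0382; 1 when adjusted over the list alone). Hmox1, the heme oxygenase, rose 4.56-fold as the sole call among 12 NRF2 targets (2.19 ± 0.24, adjusted p = 0.0182; 3 when adjusted over the list alone), and Vegfa rose 1.89-fold among 14 hypoxia genes (0.92 ± 0.12, adjusted p = 0.0350; 1 when adjusted over the list alone). The heat shock gene Hsph1 fell (-0.48 ± 0.07, adjusted p = 0.0369), the only change among 9 (1 lower and 1 higher when adjusted over the list alone). Hspa9 (adjusted p between 0.0559 and 0.232) and Hsph1 (between 0.0848 and 0.192) were called in none of the 6 fits without 1 library, Hmox1 only without WT 3 (0.0299; otherwise between 0.0527 and 0.0706) and Vegfa only without KO 3 (0.0211; otherwise between 0.0882 and 0.155), while Herpud1 lost its call without WT 1, WT 3 and KO 1 (0.0522, 0.0684 and 0.0863). Only the NRF2 list was higher by camera (adjusted p = 0.00342; adjusted p = 0.310 with an estimated correlation; fry adjusted p = 0.0392). For the endoplasmic reticulum, mitochondrial, hypoxia and heat shock lists the camera adjusted p was 0.0714, 0.0686, 0.519 and 0.971. The heat shock list had a median of -0.04, which turned to 0.03 under scaling by library totals, and a mean of 0.13.

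No gene of glycolysis (22 tested), the tricarboxylic acid cycle (18), sterol synthesis (21) or the interferon response (13) was called by edgeR, and Ndufs5 was the only call among 73 nuclear-encoded subunits of the respiratory chain. At an unadjusted p below 0.05 the first 4 lists held 3, 2, 6 and 0 higher genes and 3, 2, 0 and 0 lower ones. DESeq2 called 3, 1, 1 and 0 of their members higher and 1, 0, 0 and 0 lower, and limma called none. Glycolysis had a median of -0.03 (0.03 under scaling by library totals) and a mean of 0.04, the interferon list 0.03 and -0.12, and the respiratory chain 0.01 and -0.02. The camera adjusted p was 0.977, 0.589, 0.266, 0.971 and 0.977 in the order given, and adjusted over the list alone the calls were 1 lower in glycolysis, 1 lower in the respiratory chain and 0 elsewhere. Genes of the cytosolic ribosome, whose reads can be shared with pseudogenes, had positive fold changes in 62 of 63 cases, with a median of 0.36. Rpl17 (0.54 ± 0.08, adjusted p = 0.0456) and Rps15 (0.47 ± 0.07, adjusted p = 0.0488) rose, and 56 rose when adjusted over the list alone. The ribosome list was higher at the preset correlation (adjusted p = 3.08e-33) and not with an estimated one (adjusted p = 0.356 with an estimated correlation; fry adjusted p = 0.0371). Without 1 library, Rpl17 was called only when KO 2 was left out (adjusted p = 0.0487; otherwise between 0.108 and 0.260) and Rps15 never (between 0.0872 and 0.257).

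No p53 target (26 tested) or cell cycle gene (29) was called by edgeR, although both lists were higher by camera with a preset correlation (adjusted p = 4.08e-04 for each). With an estimated correlation neither list passed (adjusted p = 0.392 with an estimated correlation for p53 targets and 0.685 for the cell cycle), and fry gave adjusted p = 0.0745 and 0.435. At an unadjusted p below 0.05 there were 9 higher p53 targets and 0 cell cycle genes, DESeq2 called 7 and 0, limma called none, and adjusted over the list alone the counts were 5 and 0. The cell cycle call ended without WT 2 (adjusted p = 0.234). No immediate early gene (12 tested) was called by edgeR or limma and DESeq2 called 1, with 5 higher at an unadjusted p below 0.05 and 1 when adjusted over the list alone; the list was higher by camera (adjusted p = 0.00130; adjusted p = 0.186 with an estimated correlation; fry adjusted p = 0.00724).

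Few microglial markers rose in KO, while all those tested had positive fold changes. Cx3cr1, the fractalkine receptor, rose 2.04-fold, from 11.7 ± 1.67 to 23.8 ± 2.89 CPM (log2 fold change 1.03 ± 0.15, adjusted p = 0.0395), and Fcrls rose 1.88-fold (0.91 ± 0.12, adjusted p = 0.0369). These were the only calls among 14 tested markers of microglia and macrophages, all of which had positive fold changes with a median of 0.89 (11 rose when adjusted over the list alone, and DESeq2 called 10). All 12 markers of endothelium also had positive fold changes, with a median of 0.41. Of these, 8 had an unadjusted p below 0.05 and none was called (camera adjusted p = 3.05e-05; adjusted p = 0.460 with an estimated correlation). The microglial list was higher at the preset correlation (adjusted p = 8.32e-10) and not with an estimated one (adjusted p = 0.356 with an estimated correlation; fry adjusted p = 0.0617), and no microglial marker was called in the fits that left out WT 1, WT 2, WT 3, KO 1, KO 2 or KO 3. Among the 10 largest increases under the naming rule were Clec7a, a pattern receptor of myeloid cells (0.365 ± 0.122 to 3.04 ± 0.457 CPM, log2 fold change 3.07 ± 0.32, adjusted p = 0.0129), and the chemokine gene Ccl6 (2.27 ± 0.35, adjusted p = 0.0495). Clec7a was not called without WT 3, KO 1 or KO 2 (adjusted p = 0.0781, 0.0960 and 0.0539), and Ccl6 was called only without WT 2 (adjusted p = 0.0453).

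The libraries also differed in the level of midbrain genes. En1 and En2 were chosen after their values were seen. En1, a marker of midbrain and anterior hindbrain, was found at 18.6, 10.4 and 1.71 CPM in WT 1 to WT 3 and at 0.112, 0.858 and 0.960 CPM in KO 1 to KO 3, and En2 at 45, 19.9 and 1.02 CPM and 0.0699, 0.683 and 0.0784 CPM. None of the 4 tested hindbrain and midbrain genes was called by edgeR or limma, while DESeq2 called 3 lower, as many as at an unadjusted p below 0.05 and when adjusted over the list alone. The list was lower at the preset correlation (adjusted p = 0.00165) and not with an estimated one (adjusted p = 0.460 with an estimated correlation; fry adjusted p = 0.192).

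No marker of neurons (24 tested), GABAergic neurons (13), endothelium (12), erythroid cells (10) or skeletal muscle (9) was called by edgeR or limma-voom, and limma on log2(TPM + 1) called 2 neuron genes lower. Camera at the preset correlation placed the neuron list lower (adjusted p = 7.67e-04) and the other 4 higher (adjusted p = 0.00215, 3.05e-05, 0.0223 and 8.78e-04), and none passed with an estimated correlation (adjusted p = 0.473, 0.491, 0.460, 0.502 and 0.491 with an estimated correlation). Fry gave adjusted p = 0.179, 0.213, 0.129, 0.280 and 0.280. At an unadjusted p below 0.05 these lists held 6 lower genes and 4, 8, 2 and 6 higher ones, DESeq2 called 5, 2, 5, 2 and 4, and adjusted over the list alone the counts were 1, 2, 6, 0 and 0. The erythroid list had a mean of -0.10 against a median of 0.59. Its call ended without WT 3, KO 2 or KO 3 (adjusted p = 0.132, 0.0594 and 0.0627), and that of GABAergic neurons without KO 2 (0.119). The camera adjusted p was 0.977 for radial glia, 0.589 for intermediate progenitors, 0.0929 for oligodendrocyte precursors, 0.116 for astrocytes, 0.0982 for pericytes, 0.726 for meninges and fibroblasts, 0.180 for choroid plexus, 0.837 for cartilage and epidermis, 0.837 for pituitary and eye, and 0.618 for sex-linked genes. No member of these 10 lists was called by edgeR; DESeq2 called 1 radial glia gene and 1 oligodendrocyte precursor gene lower, as many as when adjusted over each list alone, and limma on log2(TPM + 1) called 1 radial glia gene. At an unadjusted p below 0.05 these lists held 1 lower radial glia gene, 1 higher and 2 lower oligodendrocyte precursor genes, 1 lower astrocyte gene, 1 higher pituitary and eye gene and 0 others. The meninges list, whose direction was up in the test with all libraries, was lower without KO 3 (adjusted p = 0.00311).

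**Figure D4:**
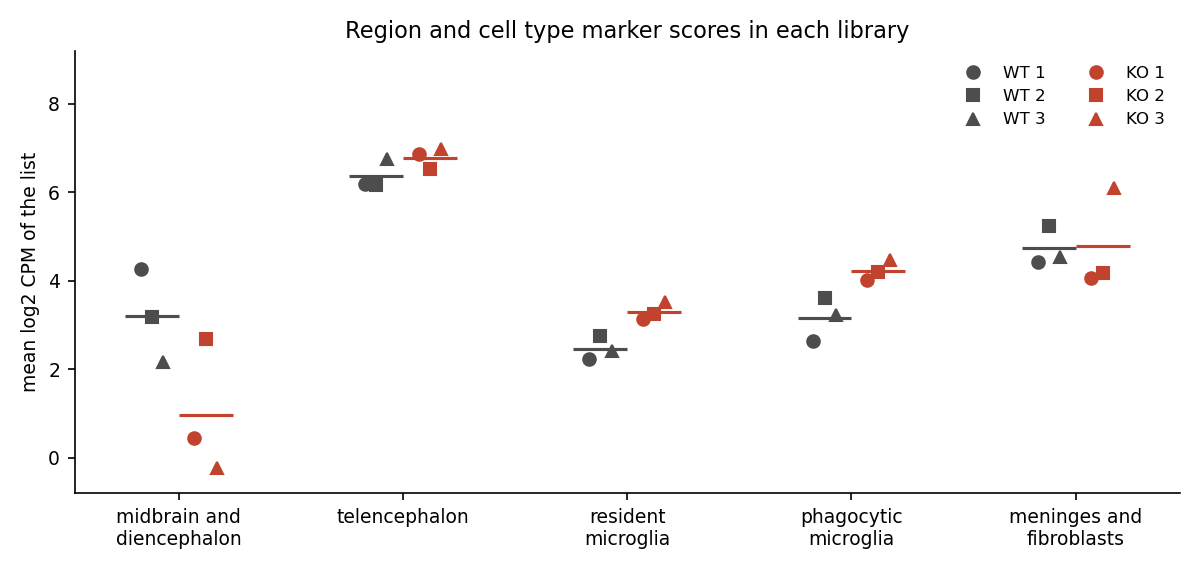
Mean log2 CPM in each library of 5 marker lists, with WT in grey, KO in red, a symbol per replicate and a bar at each group's mean. The midbrain and diencephalon score spans 4.26 in WT 1 to -0.24 in KO 3 with KO 2 above WT 3, while both microglial scores are higher in every KO library than in every WT library.

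Beside E4f1 on chromosome 17, 2 of 15 tested neighbours changed. Dnase1l2, a deoxyribonuclease gene whose RefSeq span lies 14 bases from that of E4f1, rose 2.5-fold, from 10.8 ± 0.627 to 26.9 ± 0.845 CPM (log2 fold change 1.32 ± 0.08, adjusted p = 0.00197). Rnps1, an RNA-binding protein gene 17879 bases from E4f1, fell from 122 ± 3.14 to 75.1 ± 2.87 CPM (-0.70 ± 0.06, adjusted p = 0.00567). Eci1, which lies between them and was chosen after its values were seen, had a log2 fold change of 0.41 ± 0.17 and did not pass the test (adjusted p = 0.256). Adjusted over the list alone, 1 neighbour rose and 2 fell, and camera found no shared direction (adjusted p = 0.266; fry adjusted p = 0.174). Dnase1l2 was called in all 6 fits without 1 library, and the adjusted p of Rnps1 was 0.0687 without KO 1.

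**Figure D5:**
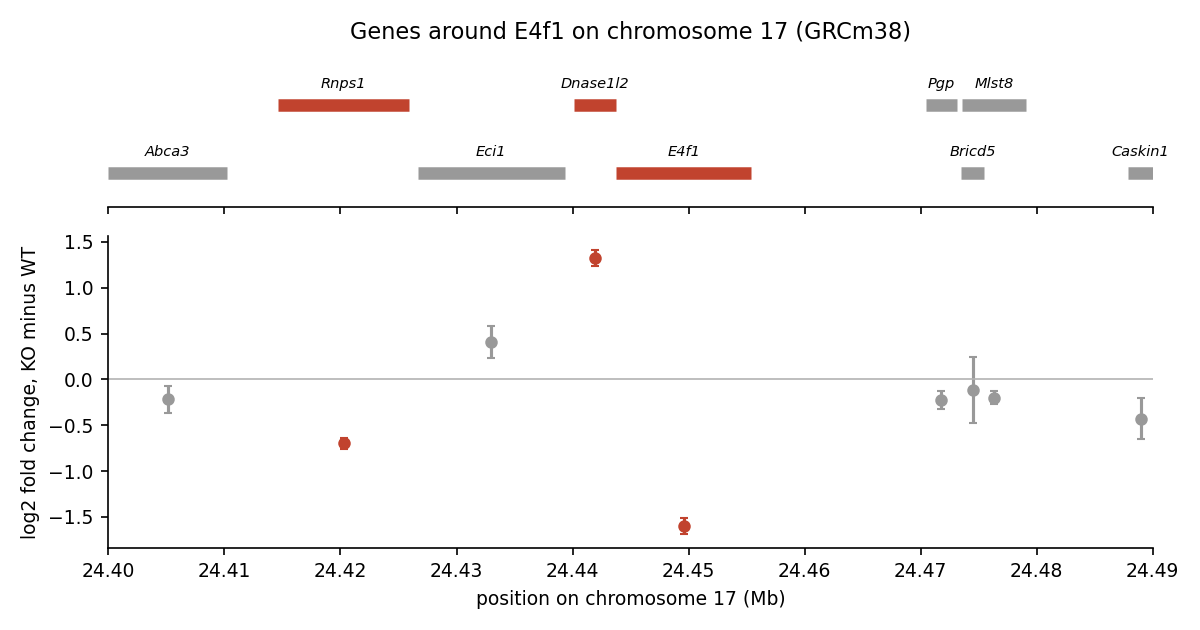
Genes around E4f1 on chromosome 17 (GRCm38, position in Mb): gene spans in the upper panel and log2 fold change (KO minus WT) ± SE in the lower panel, with genes called changed in red and others in grey. Dnase1l2 lies next to E4f1 and is higher (1.32), while E4f1 (-1.60) and Rnps1 (-0.70) are lower.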

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

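The fits without Rn45s and with the midbrain score as a covariate were chosen only after the results were seen. E4f1 kept its direction under every alternative run and its call under all except 2: with WT 1, WT 2, KO 1 and KO 2 alone its log2 fold change was -1.57 (adjusted p = 0.0721), and with the midbrain score as a covariate it was -1.65 (adjusted p = 0.219). Both fits called 0 genes in total, 0 higher, 0 lower, 0 by at least 2-fold, 0 E4F1 targets, 0 integrated stress response genes, 0 aminoacyl-tRNA synthetases and 0 microglial genes. They leave fewer residual degrees of freedom. The replicate block leaves no more and called 66 genes, so this alone does not account for the loss with the midbrain score. That block keeps all libraries. It cannot tell whether the loss with WT 1, WT 2, KO 1 and KO 2 alone comes from the smaller number of brains. The midbrain score was higher in every WT library than in every KO library, so a fit with it cannot fully separate it from genotype. Without Rn45s the 159 calls were the same genes.

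DESeq2 called 1437 genes (780 higher, 657 lower, 259 by at least 2-fold), against 159 by edgeR, and all 159 were among them. In simulated counts 28.8% of DESeq2's calls were false, a share that need not hold for the real calls. DESeq2 called 31 integrated stress response genes, 11 aminoacyl-tRNA synthetases and 10 microglial genes. Limma on log2(TPM + 1) called 245 genes (128 higher) and on log2(TPM + 0.1) 248 (128 higher, 120 lower), with 4 microglial genes in each, and each shared 154 of the 159 genes. Scaling by library totals called 186 genes, 123 of them higher (66.1% against 50.9%), with 4 microglial genes.

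The replicate number as a block left 66 genes (24 higher, 42 lower, 50 by at least 2-fold), 4 aminoacyl-tRNA synthetases and 0 microglial genes, and the Elongator list at an adjusted p of 0.0634. Deviations from the group means of same-numbered brains correlated at 0.121, 0.173 and 0.0160, and, as a hint from the data, WT 1 and WT 2 correlated best with their own number but WT 3 with KO 1, so the numbers were not taken to pair the brains. The block ended no other list test. The animal number block left 87 genes (36 higher, 51 lower), 4 aminoacyl-tRNA synthetases and 0 microglial genes.

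Without 1 library, the calls were between 36 and 82 in total, 12 and 40 higher, 24 and 42 lower, and 35 and 63 by at least 2-fold. They were between 9 and 16 in the integrated stress response, 0 and 4 among aminoacyl-tRNA synthetases, and 0 in each fit among microglial genes. Of 41 called genes named by the rule besides E4f1, between 19 and 29 kept their call in these fits, 25 with the replicate block and 41 with DESeq2 or limma, and none changed sign.

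Lists higher or lower by camera that did not pass with an estimated correlation had adjusted p = 0.356 (Elongator, ribosome and microglia), 0.186 (aminoacyl-tRNA synthetases and immediate early genes), 0.392 (p53), 0.685 (cell cycle), 0.310 (NRF2), 0.473 (neurons), 0.491 (GABAergic neurons and muscle), 0.460 (hindbrain and midbrain, endothelium) and 0.502 (erythroid). Fry gave 0.0745 (p53), 0.435 (cell cycle), 0.179 (neurons), 0.213 (GABAergic neurons), 0.192 (hindbrain and midbrain), 0.0617 (microglia), 0.129 (endothelium), 0.280 (erythroid and muscle) and 0.00724 (pyruvate). On limma-voom values the Elongator list had 0.0514 and the hindbrain and midbrain list 0.0540. Without genes shared between lists the Elongator list had 0.313, and without a filter on low counts the pyruvate list had 0.00599. With the midbrain score as a covariate the Elongator list had 0.0758, p53 targets 0.0967, the cell cycle 0.308 and GABAergic neurons 0.0762, and the hindbrain and midbrain list turned from lower to higher (0.308), which says nothing about it, since the score is built from 3 of its members. Without 1 library the adjusted p was between 0.0282 and 0.195 (pyruvate), 0.0109 and 0.0902 (Elongator), 5.60e-08 and 0.234 (cell cycle), 2.23e-06 and 0.119 (GABAergic neurons), and 4.12e-04 and 0.132 (erythroid). The meninges list, higher and not called, was lower without KO 3 (adjusted p = 0.00311, the range without 1 library being up to 0.844). The E4F1 target and integrated stress response lists passed each alternative run on the list tests, which were an estimated correlation, fry, limma-voom values, RLE scaling, no filter, both blocks, the midbrain covariate, lists without shared genes and leaving out each library. Where no cause is named here, the cause was not tested.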

Other observations

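Of the tests below, those on connective tissue and on the share of neural cells were chosen only after the result was seen, and the value of Pgp, 1 of the neighbours of lower genes, had been seen before that test was set. Several genes not yet described, chosen after their values were seen, also changed in KO (edgeR, n = 3 per group). Mrpl15, a mitochondrial ribosomal protein, had a log2 fold change of -2.39 ± 0.18 (adjusted p = 0.00384), the cardiolipin synthase Crls1 -1.44 ± 0.13 (adjusted p = 0.00683), Pdss2, of coenzyme Q synthesis, -1.40 ± 0.19 (adjusted p = 0.0341) and the mitochondrial protein gene Hax1 -1.05 ± 0.10 (adjusted p = 0.0112). Crls1 and Taz act on the same lipid, cardiolipin. Pbrm1, a subunit of a SWI/SNF complex, had -1.38 ± 0.09 (adjusted p = 0.00210) and Dpy30, a subunit of histone methyltransferase complexes, -1.07 ± 0.08 (adjusted p = 0.00252). Gpt2, the mitochondrial alanine transaminase, which moves an amino group between glutamate and pyruvate, rose by 0.83 ± 0.06 (adjusted p = 0.00252). Mrpl15, Pbrm1, Dpy30 and Gpt2 were called in all 6 fits without 1 library, and Crls1 lost its call without KO 1 (adjusted p = 0.0753). Pdss2 was called only without KO 2 (0.0463; otherwise between 0.0918 and 0.170), and Hax1 lost its call without WT 1, WT 3, KO 1 and KO 2 (0.0533, 0.0760, 0.107 and 0.0539). No enrichment of these groups was tested.

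Single libraries stood apart in some genes, and all genes in this paragraph were chosen after their values were seen. Hbb-y, an embryonic globin, was at 374 CPM in WT 1 and between 1.65 and 28.2 CPM in the others. Col1a1 was at 3015 CPM in KO 3 and 1419 CPM in WT 2, against 141 to 451 CPM elsewhere. Krt5 was at 49.7 CPM in WT 3 and the ribosomal RNA precursor Rn45s took 5.23% of its counts, against 0.520% to 2.48% elsewhere. Xist was at 16.2 CPM in KO 2, which holds Ddx3y, against 0.365 and 0.451 CPM in the 2 WT libraries that hold it. Gpr17, of committed oligodendrocyte precursors, instead differed by group without being called. It was between 3.79 and 15.1 CPM in WT and between 0.490 and 1.19 CPM in KO (adjusted p = 0.0631).

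With 3 brains against 3 there are 10 splits of the libraries, too few for a share under 0.05. The real split called 159 genes and the highest of the others 4, and 1 of the 10 splits, the real one, gave as many.

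Dnase1l2 was higher and Rnps1 lower beside E4f1. Annotated exons of these 2 genes share 0 bases with those of E4f1 in GENCODE. In RefSeq, whose transcripts the deposited tables list, their spans lie 14 and 17879 bases from that of E4f1. Both argue against reads counted for the wrong gene through overlapping exons. A stretch of another mouse strain around the targeted allele may also change neighbours: besides these 2 genes and E4f1, 3 of 191 tested genes within 5 Mb were called (1.57%, exact 95% interval 0.325% to 4.52%), against 0.990% on other chromosomes (one-sided Fisher's exact p = 0.297), and with so few calls an effect of the strain cannot be told apart from none. An effect of the allele itself on adjacent transcription, and reads running past the end of E4f1 into Dnase1l2 on the same strand, stay open and were not tested.

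The microglial scores were higher in KO and the endothelial one less so. This argues against a lower share of neural cells, raising all other types alike, as the whole cause. The resident score minus the endothelium score shifted by 0.45 ± 0.14, beyond 2 SE also without any 1 library. Its exact permutation p was 0.1, two-sided, the smallest possible, so this evidence is limited. The endothelium score itself shifted by 0.39 ± 0.15, so part of the rise stays open. More connective tissue with its macrophages stays open for KO 3. The resident score of 11 genes was higher in each KO library (shift 0.84 ± 0.19). The meninges and fibroblast score was 4.42, 5.25 and 4.54 in WT 1 to WT 3 and 4.07, 4.18 and 6.10 in KO 1 to KO 3. The first minus the second shifted by 0.80 ± 0.56, within 2 SE, by 1.35 ± 0.11 without KO 3 and by 0.52 ± 0.84 without KO 1 or KO 2. In KO 1 and KO 2 the meninges score lay below every WT library. Their resident scores, 3.14 and 3.26, lay above those of WT 1 to WT 3 (2.23, 2.75 and 2.40). These values argue against this source in KO 1 and KO 2, while in KO 3 it cannot be told apart. Myh3, of muscle, was at 7.27 and 12 CPM in KO 2 and KO 3 and between 0.727 and 1.56 CPM in the others, and muscle as a source was not tested. Whether a higher share of microglia with an unchanged profile accounts for the lists could not be decided. A score of 14 phagocytic genes minus the resident score moved by 0.24 ± 0.15, within 2 SE. Without WT 1 this difference moved by 0.09 ± 0.03, beyond 2 SE. All 3 KO libraries lay above all 3 WT libraries (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The 14 genes moved unlike each other, and their mean cannot exclude a changed profile. Fabp5 (167 CPM in WT) had -0.34 ± 0.07 and Apoe (87.4 CPM) 0.39 ± 0.32. Spp1 had 2.66 ± 0.90 (edgeR adjusted p = 0.192) and Ccl3 2.14 ± 0.51 (0.115). These genes were chosen after their values were seen. A change of state in part of the microglia stays open too: Gpnmb, of the phagocytic list, had a log2 fold change of 3.51 ± 0.54 (adjusted p = 0.0516), Clec7a 3.07 ± 0.32, and Itgax 3.28 ± 0.39 (adjusted p = 0.0221, below 0.05 without 1 library only when KO 3 was left out, 0.0497, and otherwise between 0.0550 and 0.133), Myh3, Gpnmb and Itgax being chosen after their values were seen.

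Midbrain and diencephalon genes had mostly negative fold changes, though none of the 22 was called by edgeR or limma (smallest edgeR adjusted p = 0.184, Pou4f2, chosen after its value was seen), against 4 at an unadjusted p below 0.05 and 2 by DESeq2. Of the 22 genes, 21 were negative, with a median of -1.65 ± 0.31 (SE over genes, which vary together, so it does not measure the spread between brains), and their score shifted by -2.24 ± 1.07 with overlapping groups (exact permutation p = 0.2, two-sided, with 0.1 the smallest possible). The score of 12 telencephalon genes shifted by 0.41 ± 0.23 (exact permutation p = 0.2). Of these genes, edgeR called only Gsx2, chosen after its value was seen (1.26 ± 0.19, adjusted p = 0.0456). It was called in no fit that left out 1 library. A different extent of dissection may be the cause: the midbrain score varied by 2.09 among WT and by 2.92 among KO libraries, and KO 2 (2.69) lay above WT 3 (2.17). The range within WT was slightly below the difference between groups, and that within KO was above it. The separate score of En1, En2 and Pax5 was higher in every WT library than in every KO library. Dissection and an effect of the genotype on these regions therefore cannot be told apart.

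Tube1 and Fam229b start head to head, which raised the hypothesis that genes lower in KO share promoters with lower neighbours. In GENCODE, 7 other genes called lower had a tested neighbour starting within 1000 bases on the opposite strand, and all 7 neighbours had negative fold changes, with a median of -0.25 against 0.01 for 1248 such neighbours of genes not called (10000 random sets matched on expression, one-sided permutation p = 0.00220). Without Pgp, paired with E4f1 itself, the median was -0.41. This pair is close in GENCODE only. In RefSeq, E4f1, on the minus strand, ends at 24455392 and Pgp begins at 24470426. The permutation p includes the pair. None of the 7 was called by edgeR. Of them, 2810408A11Rik beside Neurl4 had -1.07 ± 0.17 (adjusted p = 0.0538), Itfg1 beside Phkb -0.61 ± 0.11 and Fbxo9 beside Ick -0.57 ± 0.10, these genes being chosen after their values were seen. The others moved less: Myo9a beside Senp8 had -0.25 ± 0.09, Pgp -0.22 ± 0.10 and Slc31a1 beside Fkbp15 -0.17 ± 0.08. Apopt1, which starts 4 bases from Bag5, had -0.02 ± 0.10. A shared promoter may lower such neighbours, a hypothesis that rests on few genes; reads shared between opposite strands were not tested.

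A shortage of Elongator might lower transcripts rich in the codons its tRNAs read, the AA-ending codons of lysine, glutamine and glutamate. Across 14235 genes, which are not independent replicates, Spearman's rho between the share of these codons and the log2 fold change was -0.00511, and other splits of the libraries gave rho of up to 0.172 in size. With the share of G and C at the third codon position held fixed, rho was -0.0358, and other splits gave up to 0.0569 in size. No relation at the mRNA level stood out from the other splits. With 10 splits, and values of this size from the others, a weak relation could not be seen. Translation was not measured here.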
